A study of Rattus norvegicus with 24 samples.

How the data were processed

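RNA from the ventricles of 24 male Wistar rats was measured on Affymetrix RG-U34A oligonucleotide arrays, 1 array per animal. Rats were injected with streptozotocin, a toxin that destroys the insulin-producing beta cells of the pancreas, or with citrate buffer alone, and ventricles were collected 3, 28 or 42 days later. Each of the 6 groups held 4 animals. The deposited table gives, per the submitters' processing notes, a MAS5 signal for each probe set, a linear intensity per array. The MAS5 version is not given in the sources used here. The table held 8799 probe sets and 24 arrays, and each array's mean after trimming 2% at each end lay between 1499.9 and 1500, so the arrays had been scaled to a common mean. The deposited run-setting files of the 24 arrays were read only for scan day, fluidics station, chip lot and operator. Body weight, ventricle weight and blood glucose came from the labels.

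Of the 8740 probe sets that were not array controls, 7006 matched 1 gene symbol, 308 matched several and 1426 matched none in the annotation used. The 59 control probe sets were left out of the comparisons. Signals were floored at the pooled 10th percentile of all values, 30.5, and converted to log2 (floor 4.93). Probe sets with a mean log2 value at or above the 40th percentile were kept, which left 5244. A model of group means was fitted over all 24 arrays with limma 3.58.1 in R 4.3.3, with 18 residual degrees of freedom and moderated variances (eBayes with trend and robust options, median prior degrees of freedom 6). Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each comparison, and the threshold was an adjusted p under 0.05. Comparisons were diabetic against control at each day, the difference of that effect between days as an interaction, and day 42 against day 3 within controls and within diabetic animals.

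Gene lists covering metabolic pathways, stress responses, cardiac functions and cell type markers were fixed with the main model, the comparisons and most alternative settings before the data were examined. There were 42 lists. Apart from the ribosomal proteins they held 783 entries, with a gene counted once for each list it is on, and 574 entries were on the array. The 37 lists with at least 4 measured genes were tested. The list test was camera in limma with a preset correlation of 0.01, on 3140 genes with 1 probe set each, the one with the highest mean. It was repeated with an estimated correlation, and fry was run beside it. Members were also counted after p-values were adjusted over the list alone.

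Genes were named by a fixed rule. It took the 10 largest rises and the 10 largest falls at each day among genes past the threshold whose 4 diabetic arrays all lay beyond the 4 control arrays. It added up to 4 members of each list discussed, by smallest adjusted p, and a short set of cardiac and fuel genes. For differences between days and for the course with age it took the 5 largest each way. Each gene was represented by the probe set with the highest mean, and other probe sets are mentioned where they differ most in size or in passing the threshold. Probe set identifiers are not printed. Probe sets without a single symbol are outside these ranks, and 5, 19 and 98 of them passed at days 3, 28 and 42. Genes outside the rule are named as chosen after their values were seen.

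Animal measures and array quality were compared by an exact two-sided permutation test of the difference of means, with 70 arrangements per day, using scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15. Figures were drawn with matplotlib 3.10.9.

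Alternatives covered the floor (none, the 25th percentile, or a pseudocount of 93.6), the filter (none, or the 60th percentile), quantile normalization, median centring, plain eBayes, a fit of only the groups compared, 1 probe set per gene, stricter thresholds, and leaving out each array in turn. Blocks for replicate number, scan day and fluidics station were tried as well. Chip lot blocks, fits within single batches, and a fit without the 2 arrays that deviate most from their group means were added after the data were seen. The pipeline was tested on simulated data with known changes. For a day 42 comparison limma recovered 31.8% of changes of 1.5-fold, 69.4% of 2-fold and 95.6% of 4-fold, and 4.7% of its calls were false. For a difference between days it recovered 43.7% of the same changes, so 0 calls there do not show that effects were equal. Camera called the shifted list in all 10 runs, and 8 unshifted lists over those runs. Genes were simulated independently, so these runs do not show how often camera calls lists of correlated genes. When the real arrays of a day were split into other groups, the preset correlation called a median of 4, 3 and 9.5 lists at days 3, 28 and 42. The number of arrays limits the precision of every value. At the level of a probe set, the median standard error of a log2 change was 0.214 within a day and 0.303 for a difference between days.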

Results

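Signals for 8799 probe sets were measured in ventricles of 24 rats, with 4 diabetic and 4 control animals at 3, 28 and 42 days after injection of streptozotocin or buffer. Per the series description these days stand for a stage without cardiac symptoms, a stage of diastolic dysfunction and a stage of both diastolic and systolic dysfunction. The median signal of an array ran from 322.7 to 444.7 intensity units. Correlations between arrays of the same group lay between 0.927 and 0.978. Array quality measures did not differ between diabetic and control arrays at any day past the correction (smallest adjusted p = 0.64, exact permutation test), which does not show that they were equal. The hexokinase 3' to 5' ratio ran from 2.60 to 5.07 at day 42, against 1.61 to 2.77 at day 3 and 1.43 to 2.58 at day 28, in both groups.

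The diabetic animals were hyperglycaemic from day 3, and by day 42 they were far lighter than their controls, with a heart that was heavy for the body. Blood glucose was 540 ± 53.0 mg/dL (SD, n = 4) in diabetic against 127 ± 14.8 mg/dL (n = 4) in control rats at day 3, 633 ± 82.9 against 113 ± 10.1 at day 28, and 654 ± 126 against 132 ± 22.5 at day 42. Body weight at day 42 was 118 ± 6.19 g (SD, n = 4) in diabetic and 432 ± 26.8 g (n = 4) in control rats, and at day 28 it was 230 ± 28.0 g and 322 ± 24 g. Each of these differences separated all 8 animals of a day (p = 0.029, the smallest the exact permutation test can give, adjusted p = 0.038). At day 3 body weight was 151 ± 6.98 g in diabetic and 173 ± 11.6 g in control rats, which did not pass (exact p = 0.086, adjusted p = 0.10). The ventricles weighed 0.405 ± 0.0252, 0.568 ± 0.0665 and 0.367 ± 0.0222 g (SD, n = 4) in diabetic rats at days 3, 28 and 42, against 0.508 ± 0.015, 0.8 ± 0.086 and 0.997 ± 0.118 g in controls, each with exact p = 0.029 and adjusted p = 0.038. The ratio of ventricle to body weight was 3.13 ± 0.0549 mg/g (SD, n = 4) in diabetic against 2.30 ± 0.141 in control rats at day 42 (exact p = 0.029, adjusted p = 0.038). At days 3 and 28 the ratio did not pass, at 2.69 ± 0.263 against 2.94 ± 0.186 (exact p = 0.23) and 2.47 ± 0.0379 against 2.48 ± 0.138 (exact p = 0.91). The diabetic effect on the ratio was larger at day 42 than at day 3 by 1.08 mg/g (permutation within days, p = 0.0033, adjusted p = 0.039), while the difference between days 42 and 28, 0.838 mg/g, did not pass (p = 0.013, adjusted p = 0.078). That permutation shuffles labels within both days, so it tests for no effect at either day. Its p-values do not show that the effect differed between days.

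**Figure D1:**
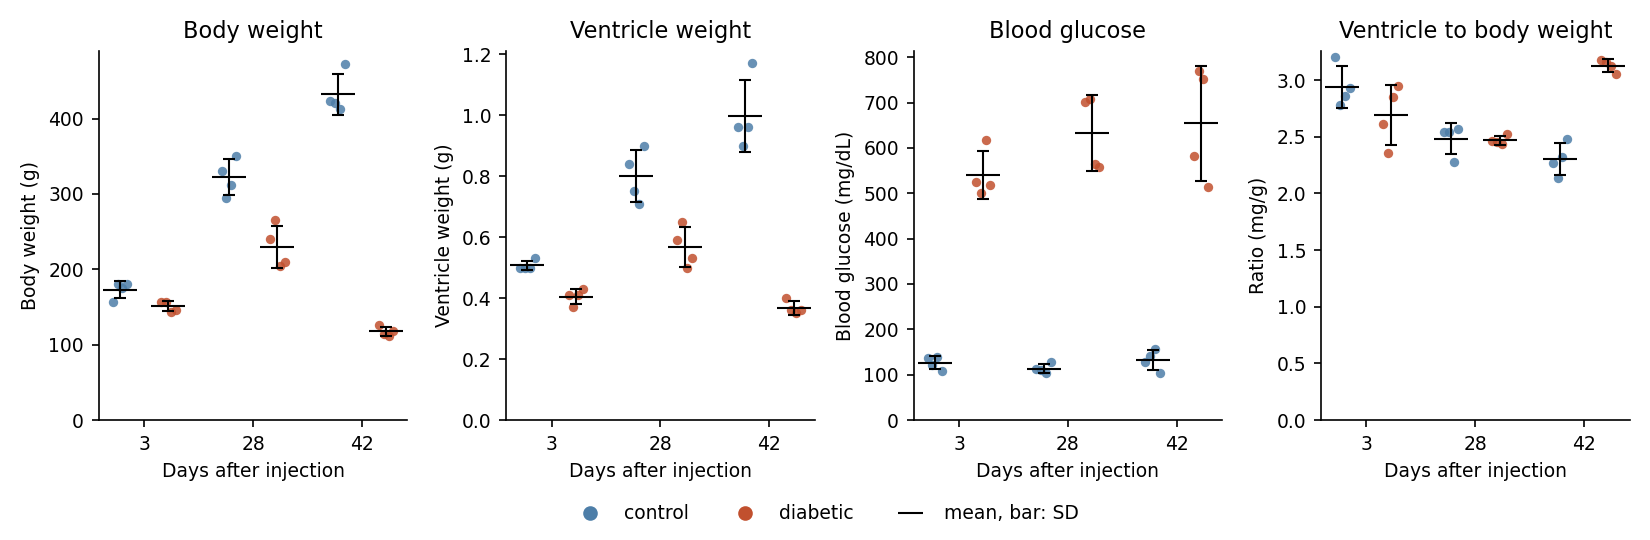
Body weight (g), ventricle weight (g), blood glucose (mg/dL) and ventricle to body weight ratio (mg/g) of each control and diabetic rat by day, with bars for mean and SD (n = 4). At day 42 the diabetic rats weighed 112 to 126 g and the controls 413 to 472 g.

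At day 3 the question is which transcripts had changed before any cardiac symptom. Genes of fatty acid oxidation were already higher in the diabetic ventricles, and the insulin-responsive glucose transporter was lower. Acot1, a cytosolic thioesterase that releases fatty acids from acyl-CoA, averaged 786 ± 513 intensity units (SD, n = 4) in diabetic and 50.6 ± 31.5 (n = 4) in control ventricles, a log2 change of 3.61 ± 0.58 (SE, adjusted p = 0.0017, limma). Acot1 lay at the floor in 2 of the 4 controls, so its log2 change ran from 2.36 to 3.81 with other floors. Slc2a4, the glucose transporter GLUT4, fell by 0.94 ± 0.18 on the log2 scale (adjusted p = 0.0074), from 6980 ± 715 to 3680 ± 730 intensity units. Pdk4, a kinase that shuts off pyruvate oxidation, rose by 1.31 ± 0.32 (adjusted p = 0.044), and the mitochondrial uncoupling protein gene Ucp3 rose by 1.03 ± 0.24 (adjusted p = 0.039). Slc2a4 did not pass with scan day (-0.82 ± 0.20, adjusted p = 0.08) or fluidics station (-0.79 ± 0.21, adjusted p = 0.11) as a block, nor without diabetic replicate 2 (-0.89) or diabetic replicate 3 (-0.83). All 4 diabetic arrays of day 3 and 1 control array ran on station 2, and 3 controls on station 1. With 1 array left out Pdk4 passed only without control replicate 4, and Ucp3 only without control replicate 4 or diabetic replicate 4, and scan day as a block ended both calls (1.44 and 1.01).

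Other large rises at day 3 were in Penk, the precursor of the enkephalin opioid peptides, with 2.22 ± 0.36 (4.67-fold, adjusted p = 0.0018), and in Pik3c2g, a class II phosphoinositide 3-kinase, with 1.88 ± 0.28 (3.69-fold, adjusted p = 0.00086). Ivns1abp (1.29), Sult1a1 (1.20), Ephx1 (1.14), Alox15 (1.09) and Pla2g2a (1.05) completed the 10 largest rises among named genes, while a probe set without a symbol rose by 2.50. Sult1a1 and Ephx1 encode enzymes of detoxification, and Alox15 and Pla2g2a enzymes of lipid mediator formation. The largest fall of a named gene was in Cdk1, the kinase that drives cells into mitosis, from 536 ± 203 to 135 ± 45.2 intensity units (3.95-fold lower, adjusted p = 0.028). Racgap1, which acts in cytokinesis, fell by 1.11 and Casq1, the skeletal-type calcium store protein, fell by 1.11 too. Cntnap1 (-0.97), Inha (-0.77), Higd1a (-0.69), Ubqln1 (-0.64), Pcca (-0.58) and Ccng1 (-0.53) also fell. Among the heart failure markers fixed in advance, Nppa, atrial natriuretic peptide, had a log2 difference of 1.27 that did not pass (adjusted p = 0.29). The values for Nppb (-0.16), Myh6 (-0.10), Atp2a2 (-0.01), Trim63 (0.16), Cd36 (0.60) and Cpt1b (0.20) did not pass either. The main Myh7 probe set gave 0.05, while another probe set of that gene gave 2.85 and passed. The maker's identifier marks the main Myh7 probe set, like those of Myh6, as shared by similar sequences, so its values are not specific to Myh7. The probe sets used at every day for Acot1, Slc2a4, Penk and Inha are marked as shared too, so their values may not be specific to these genes. Other probe sets of Slc2a4 (-0.47), Higd1a (-0.35), Acot2 (0.85), Ucp3 (0.89) and Alox15 (1.21) had the same sign and did not pass.

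By gene group, 5 of 16 measured PPAR-alpha targets rose at day 3 and 0 fell, and 7 rose when adjusted over the list alone (camera adjusted p = 2.3e-06, adjusted p = 0.0044 with an estimated correlation). Acot1, Acot2 (0.88), Ucp3, Cpt1a (0.59) and Pdk4 were the members that rose. Of 17 fatty acid oxidation genes 3 rose, Decr1 (0.98), Eci1 (0.74) and Cpt1a, and 4 rose adjusted over the list alone (camera adjusted p = 8.1e-06, adjusted p = 0.0044 with an estimated correlation). One other Eci1 probe set had the opposite sign at each day, with values near 0. Of 17 genes of glucose uptake and glycolysis 2 fell, Slc2a4 and the muscle enolase Eno3 (-1.32), and 3 fell adjusted over the list alone (camera adjusted p = 8.1e-06, adjusted p = 0.0077 with an estimated correlation). The main probe set of the hexokinase gene Hk2 did not pass (-0.45), while another fell by 1.88 (adjusted p = 0.026). Adipocyte markers were higher: 1 of 5 rose, the lipase gene Lipe (0.77), and 4 rose adjusted over the list alone (median 0.77, camera adjusted p = 6.4e-05, adjusted p = 0.0055 with an estimated correlation). Within single batches the median log2 change of PPAR-alpha targets ran from 0.17 to 0.46 and of fatty acid oxidation genes from 0.16 to 0.21. For glycolysis genes it ran from -0.37 to -0.19 and for adipocyte markers from 0.58 to 0.87. These batches share arrays, so they are not independent checks. Station 2 and chip lots 4 and 5 each held only 1 array of a group.

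A further 9 lists passed at day 3 with the preset correlation and were lost with an estimated one. Ribosomal proteins had 0 of 40 members past the threshold and a median of 0.13 (adjusted p = 0.279 with an estimated correlation), and oxidative phosphorylation 0 of 39 and a median of -0.16 (adjusted p = 0.350 with an estimated correlation). In the cell cycle list 1 of 12 genes fell, Cdk1, and 2 adjusted over the list alone (median -0.43, adjusted p = 0.138 with an estimated correlation). In the list of glucocorticoid responsive genes 1 of 12 rose, Pdk4, and 3 adjusted over the list alone (median 0.44, adjusted p = 0.142 with an estimated correlation). For branched-chain amino acid catabolism 1 of 11 fell, Pcca, and in peroxisomal fatty acid oxidation 1 of 8 rose, the catalase gene Cat (1.5), whose diabetic and control arrays overlapped and whose other probe set did not pass (0.46). Those lists gave adjusted p = 0.247 and adjusted p = 0.142 with an estimated correlation. No member passed over all genes for the circadian clock (median 0.19, adjusted p = 0.142 with an estimated correlation), heat shock genes (-0.16, adjusted p = 0.350) or complement (0.13, adjusted p = 0.38).

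In all, 49 of 5244 probe sets passed at day 3 with limma, 33 higher and 16 lower in diabetic ventricles, and 535 had an unadjusted p under 0.05 where 262 would be expected by chance. Diabetic and control arrays were fully separated in 377 probe sets (7.2%, where chance gives 2.86%). The count rested on single arrays: it was 21 without control replicate 2, 32 without control replicate 4, 17 without diabetic replicate 2 and 18 without diabetic replicate 3. It was 20 with scan day and 23 with fluidics station as a block, and of the 27 named genes past the threshold 17 and 16 were lost. Their log2 changes with the block were 0.74 to 1.1 and 0.78 to 1.2 times those without it, and their standard errors a median of 1.08 and 1.18 times as large. Within scan day 4 it was 3, within station 2 it was 5, and within chip lots 4 and 5 it was 31 and 2, though all 49 kept their sign in each; the other scan days and stations held too few arrays of both groups. The 49 were picked in these same arrays, so signs kept within batches are no independent check. Of the 27 named genes Acot1, Cntnap1, Decr1, Ephx1, Higd1a, Penk, Pik3c2g and Sult1a1 stayed past the threshold whichever array was left out, though the station block ended the call of Higd1a. Ubqln1 was lost without diabetic replicate 2 (-0.60), Alox15 without diabetic replicate 3 (0.95), Eci1 without either (0.68 and 0.63), and the others without at least 4 of the 8 arrays or, for Slc2a4, without those same diabetic replicates.

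**Figure D2:**
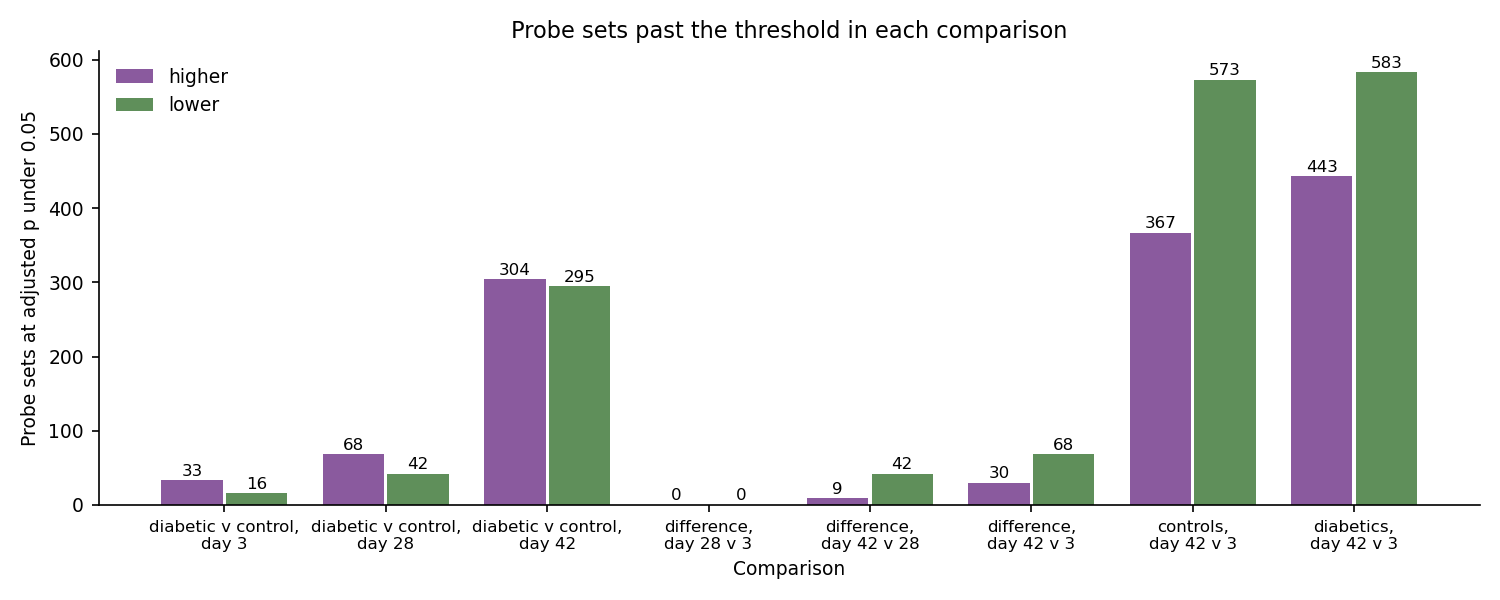
Number of probe sets past an adjusted p of 0.05 (limma, of 5244) that were higher or lower in diabetic than control ventricles at each day, with bars starting at 0. The counts were 33 and 16 at day 3, 68 and 42 at day 28, and 304 and 295 at day 42.

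At day 28, the stage of diastolic dysfunction, genes of fatty acid oxidation were higher and glucose transporter genes lower in diabetic ventricles. Acot1 averaged 1370 ± 638 intensity units (SD, n = 4) in diabetic and 87.7 ± 54.2 (n = 4) in control ventricles, a log2 change of 4.0 ± 0.58 (SE, adjusted p = 0.00016, limma; 2.96 to 4.18 with other floors, since 1 control lay at the floor). Acot2, its mitochondrial relative, rose by 1.60 ± 0.21 (adjusted p = 7.8e-05) and Decr1, which prepares unsaturated fatty acids for oxidation, by 1.33 ± 0.17 (adjusted p = 5.7e-05). Cd36, the fatty acid uptake protein, rose by 1.10 ± 0.21 (adjusted p = 0.0038) and Pdk4 by 1.43 ± 0.32 (adjusted p = 0.012). The glucose transporter genes Slc2a4 (fell by 1.06 ± 0.18, adjusted p = 0.0012) and Slc2a1 (fell by 1.22 ± 0.29, adjusted p = 0.022) were lower, as was the hexokinase gene Hk2 (-1.06, and -2.15 for another probe set).

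The remaining large rises at day 28 were Pik3c2g (2.26), C2cd4b (2.20, 1.59 to 2.20 with other floors), the carbonyl reductase gene Cbr1 (1.87), Penk (1.81), the lipolysis inhibitor gene G0s2 (1.45), Pdlim5 (1.4, and 0.56 for another probe set, not past the threshold) and Impa2 (1.35). Ranks cover named genes. Probe sets without a symbol rose by up to 3.88 and fell by up to 2.28. The largest fall of a named gene was in LOC102553868, an uncharacterised locus, from 5280 ± 506 to 1240 ± 470 intensity units (4.5-fold lower, adjusted p = 0.028). Acsl6, an acyl-CoA synthetase, fell by 1.98 ± 0.34 (adjusted p = 0.0013), and Bdh1, which oxidises the ketone body beta-hydroxybutyrate, fell by 1.88 ± 0.35 (adjusted p = 0.0026). Kcne1, a potassium channel subunit of cardiac repolarisation, fell by 1.88 (adjusted p = 0.015) and Ckb, the brain-type creatine kinase, fell by 1.47 (adjusted p = 0.0011). Pc, pyruvate carboxylase (-1.42), Ntsr2 (-1.36), Sctr (-1.35, and -2.21 for another probe set, not past) and Pxmp2 (-1.08) followed. Nppa had a difference of 1.17 that did not pass (adjusted p = 0.28), and neither did Nppb (-0.28), Myh6 (0.08), Atp2a2 (-0.03) or Trim63 (0.04). The main probe set did not pass for Ucp3 (0.65, adjusted p = 0.21) or Myh7 (0.44, adjusted p = 0.14), while another probe set did, with 1.20 for Ucp3 and 1.61 for Myh7, whose main probe set is shared by similar sequences.

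Of 17 fatty acid oxidation genes 6 rose at day 28 and 0 fell, among them Decr1, Hadha (0.81), Eci1 (0.80) and Cpt1a (0.74), and adjusted over the list alone 10 rose and 1 fell (median 0.36, camera adjusted p = 1.1e-11, adjusted p = 7.9e-05 with an estimated correlation). Cpt1b, the muscle form of the carnitine palmitoyltransferase that admits fatty acids to mitochondria, rose by 0.36 (adjusted p = 0.046), and another Cpt1b probe set did not pass (0.46, adjusted p = 0.0555). Of 16 PPAR-alpha targets 6 rose and 1 fell, and adjusted over the list alone 8 rose and 1 fell (median 0.29, camera adjusted p = 4.5e-09, adjusted p = 0.00092 with an estimated correlation). Within single batches the medians ran from 0.21 to 0.40 for fatty acid oxidation and from 0.28 to 0.34 for PPAR-alpha targets. The calls of 3 lists were lost with an estimated correlation. Ribosomal proteins had 0 of 40 members past the threshold and 3 risen adjusted over the list alone (adjusted p = 0.149 with an estimated correlation). For branched-chain amino acid catabolism 2 of 11 fell, Ivd (-0.58) and Pcca (-0.55), and 4 adjusted over the list alone (adjusted p = 0.436 with an estimated correlation). In glucose uptake and glycolysis 3 of 17 fell, Slc2a4, Slc2a1 and Hk2, and adjusted over the list alone 5 fell and 1 rose (adjusted p = 0.267 with an estimated correlation).

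At day 28 limma called 110 probe sets, 68 higher and 42 lower in diabetic ventricles, and 342 probe sets were fully separated (6.5%, where chance gives 2.86%). All 4 controls of day 28 and 1 diabetic array ran on station 2, and the other diabetic arrays on station 1. Station and diabetes were thus hard to tell apart at this day. The count of calls was 49 with fluidics station as a block and 99 with scan day as a block, and of 30 named genes past the threshold 10 and 3 were lost. Among those 10 were LOC102553868 (-2.17 ± 0.52 without and -2.44 ± 0.61 with the block), Slc2a1 (-1.22 ± 0.29 and -1.0 ± 0.34), Cpt1b (0.36 ± 0.09 and 0.36 ± 0.11), Cpt1a (0.74 ± 0.14 and 0.67 ± 0.17) and Pdk4 (1.43 ± 0.32 and 1.15 ± 0.36). The log2 changes of the 10 were 0.8 to 1.13 times as large with the block, and the standard errors a median of 1.17 times. The count was 90 within scan day 2 and 51 within chip lot 2. Within station 2, with 1 diabetic array, the log2 changes of the 110 were a median of 0.98 times those of the full fit. All 110 kept their sign in each batch, but they were picked in these same arrays, so this is no independent check. Leaving out single arrays gave 79 to 116. Cpt1b, Kcne1, LOC102553868, Ntsr2, Pcca, Pdk4, Sctr and Slc2a1 were no longer past the threshold without one or other array, and the other 22 of the 30 stayed past it. For Pdk4 the array was control replicate 1 alone (1.12), and for Kcne1 control replicate 1 (-1.74), control replicate 2 (-1.72) or diabetic replicate 2 (-1.43), while the others were lost without at least 4 of the 8 arrays.

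At day 42, with both systolic and diastolic dysfunction, genes of collagen, antigen presentation, heat shock and the clock were lower in diabetic ventricles, as were glucose transporter genes, and PPAR-alpha targets and a natriuretic peptide were higher. Acot1 averaged 3880 ± 1430 intensity units (SD, n = 4) in diabetic and 46.6 ± 28.6 (n = 4) in control ventricles, a log2 change of 6.31 ± 0.58 (SE, adjusted p = 4.7e-08, limma; 4.77 to 6.54 with other floors, since 2 controls lay at the floor). Pdk4 rose by 3.21 ± 0.32 (9.25-fold, adjusted p = 1.8e-07), while Slc2a4 fell by 1.81 ± 0.18 (3.52-fold lower, adjusted p = 1.7e-07). Nppa, a marker of ventricular stress, averaged 36200 ± 4660 against 7660 ± 2530 intensity units (4.93-fold, adjusted p = 0.0017), and 3 other Nppa probe sets gave 2.22 to 2.90. Col3a1, the fibrillar collagen of type III, averaged 2270 ± 1580 in diabetic against 14100 ± 1810 in control ventricles (7.20-fold lower, adjusted p = 5.6e-08).

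**Figure D3:**
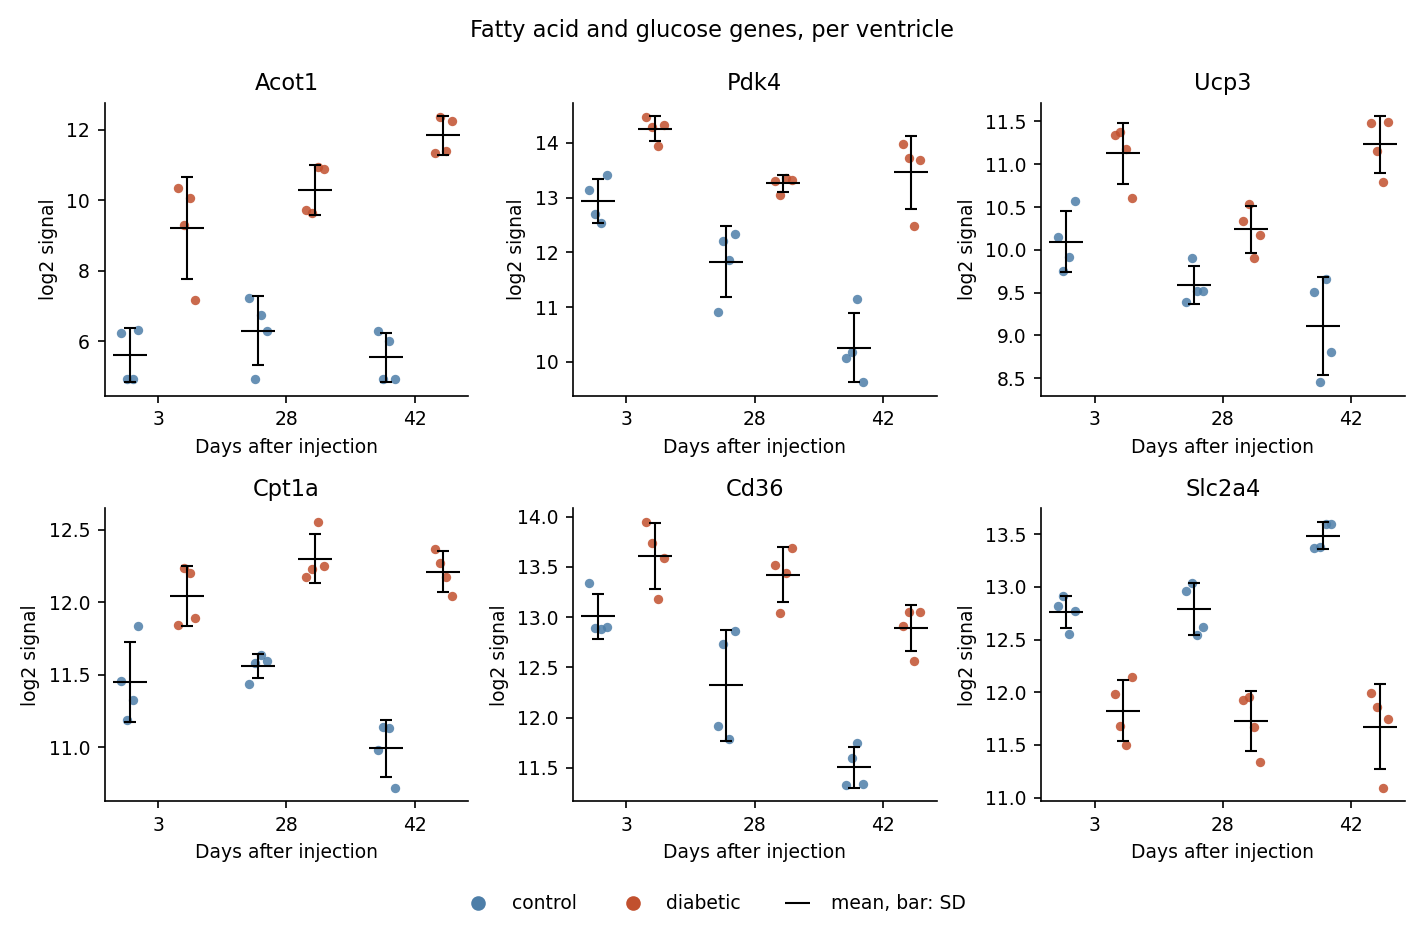
Signal (intensity, log scale) of Acot1, Pdk4, Ucp3, Cpt1a, Cd36 and Slc2a4 in each control and diabetic ventricle by day, with bars for mean and SD (n = 4). Acot1 averaged 786, 1370 and 3880 in diabetic ventricles at days 3, 28 and 42, and 50.6, 87.7 and 46.6 in controls.

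The other large rises at day 42 were Pik3c2g (2.90), Penk (2.57), the cytochrome P450 gene Cyp2e1 (2.38, adjusted p = 1.7e-06), the aromatic amino acid decarboxylase gene Ddc (2.27), C2cd4b (2.21), Ucp3 (2.13) and Acot2 (1.93). Ranks cover named genes, and probe sets without a symbol rose by up to 7.08 and fell by up to 6.68. The largest fall of a named gene was in LOC102553868, with -6.22 (-6.23 to -4.96 with other floors, since 1 diabetic array lay at the floor). Hspa1a, the inducible heat shock protein of the Hsp70 family, averaged 1290 ± 348 against 20100 ± 3960 intensity units (15.8-fold lower, adjusted p = 3.4e-05). RT1-Da, an MHC class II chain (-2.98), the clock output factor Dbp (-2.94), Acsl6 (-2.51, -2.51 to -1.81 with other floors), the immediate early gene Nr4a1 (-2.49, adjusted p = 0.045, and 0.054 with a pseudocount), the class II invariant chain Cd74 (-2.45), the potassium channel gene Kcnd3 (-2.40, -2.40 to -1.61 with other floors) and Bdh1 (-2.27) completed the 10 largest falls. Values for Nppb (0.57, adjusted p = 0.16), Myh6 (-0.08), Myh7 (0.30), Atp2a2 (-0.17), Trim63 (0.10) and Cpt1b (0.23) did not pass. Another Myh6 probe set fell by 0.84 (adjusted p = 7.3e-06), and another Myh7 probe set gave 0.96 and did not pass (adjusted p = 0.054).

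**Figure D4:**
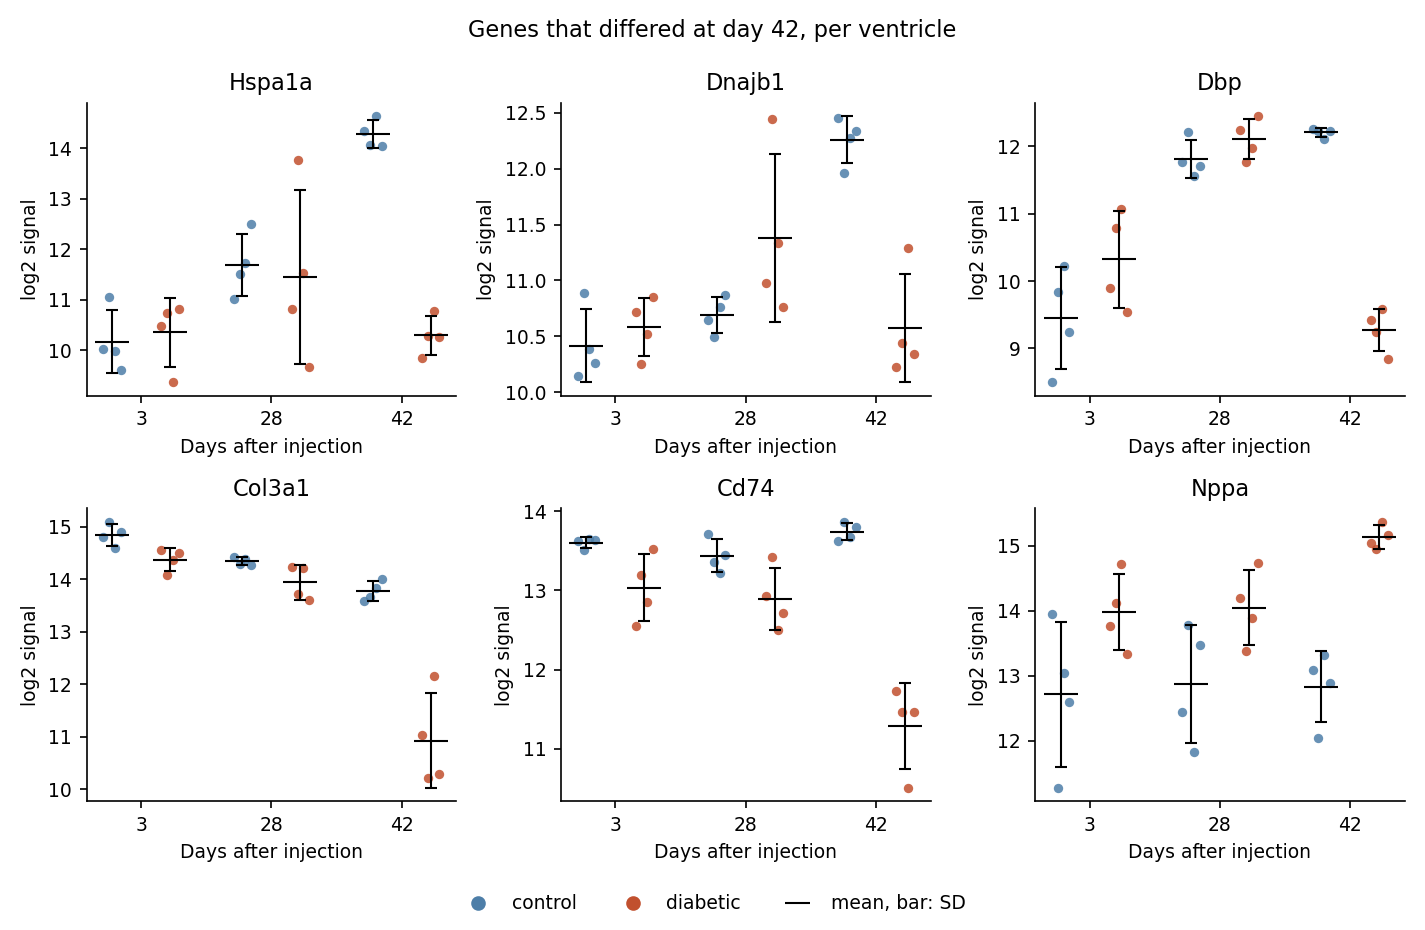
Signal (intensity, log scale) of Hspa1a, Dnajb1, Dbp, Col3a1, Cd74 and Nppa in each control and diabetic ventricle by day, with bars for mean and SD (n = 4). At day 42 Hspa1a averaged 20100 in controls and 1290 in diabetic ventricles, and Nppa 7660 and 36200.

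Among lists that held at day 42, ribosomal proteins were higher: 19 of 40 rose and 1 fell, the muscle paralog Rpl3l (-0.77, chosen after its value was seen), and adjusted over the list alone 28 rose and 1 fell (median 0.43, camera adjusted p = 5.8e-14, adjusted p = 0.0368 with an estimated correlation). Rps16 (0.71), Rpl7a (0.67), Rpl19 (0.59) and Rps9 (0.54) are examples. Of 16 PPAR-alpha targets 8 rose and 2 fell, and adjusted over the list alone 9 rose and 2 fell (median 0.52, camera adjusted p = 8.6e-07, adjusted p = 0.0102 with an estimated correlation), with Cd36 at 1.39 and Cpt1a at 1.22. Of 11 genes of branched-chain amino acid catabolism 8 fell, and 8 adjusted over the list alone, such as Acadsb (-1.49), Pcca (-0.77), Ivd (-0.74) and Auh (-0.49) (median -0.63, camera adjusted p = 9.2e-06, adjusted p = 0.0383 with an estimated correlation). Adipocyte markers were higher: 4 of 5 rose, and 4 adjusted over the list alone, which were Cfd (1.82), Lipe (0.91), Fabp4 (0.77) and Cidea (0.50) (camera adjusted p = 0.0039, adjusted p = 0.0368 with an estimated correlation). Within fluidics stations 1 and 2 the medians ran from 0.33 to 0.51 for ribosomal proteins, 0.49 to 0.59 for PPAR-alpha targets, -0.69 to -0.58 for branched-chain catabolism and 0.73 to 0.77 for adipocyte markers.

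Chaperone genes were lower at day 42: 7 of 20 heat shock genes fell and 0 rose, and 10 fell adjusted over the list alone, with Hspa1a, Hsph1 (-2.06), Dnajb1 (-1.68) and Dnaja1 (-1.30) as examples (median -0.39, camera adjusted p = 3.4e-07, adjusted p = 0.0368 with an estimated correlation). In the list of interferon and antigen presentation genes 7 of 16 fell, and 10 adjusted over the list alone (median -0.78, camera adjusted p = 4.7e-07, adjusted p = 0.0383 with an estimated correlation). RT1-Da, Cd74, RT1-Db1 (-1.79) and RT1-Bb (-1.35, other probe sets -2.83 to -0.61), which load and present peptides to helper T cells, were among them. Of 8 circadian clock genes 3 fell, Dbp, Bhlhe41 (-1.83) and Bhlhe40 (-0.94), and 5 adjusted over the list alone (median -1.04, camera adjusted p = 0.00037, adjusted p = 0.0368 with an estimated correlation), while Per2 at -0.90 did not pass over all probe sets (adjusted p = 0.074). Of 7 genes that thyroid hormone induces 2 fell, Slc2a4 and the malic enzyme gene Me1 (-0.52), and 3 adjusted over the list alone (median -0.52, camera adjusted p = 0.0074, adjusted p = 0.0368 with an estimated correlation). Within stations the medians ran from -0.49 to -0.35 for heat shock genes, -0.91 to -0.41 for antigen presentation, -1.12 to -0.97 for clock genes and -0.45 to -0.30 for thyroid hormone induced genes, the last past the threshold in 1 of 2 stations.

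The fibroblast marker list passed at day 42 through its matrix genes. Of 8 markers 5 fell, and 5 adjusted over the list alone: Col3a1, Col1a2 (-2.10), Col1a1 (-1.74), Lum (-1.67) and Dcn (-0.49) (median -1.08, camera adjusted p = 9.2e-06, adjusted p = 0.0383 with an estimated correlation, -1.09 to -1.08 within stations). The cell markers Thy1 (-0.47), Pdgfra (0.03) and Tcf21 (0.47), named with Dcn after their values were seen, did not pass. In the extracellular matrix list, which shares the collagens and Lum, 11 of 26 fell and 3 rose, and adjusted over the list alone 12 fell and 3 rose (median -0.40, camera adjusted p = 8.1e-05, adjusted p = 0.128 with an estimated correlation). Col15a1 (-2.19) was the member with the smallest adjusted p.

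The calls of 6 more lists at day 42 were lost with an estimated correlation. In oxidative phosphorylation 1 of 39 rose, Atp5if1 (0.87), an inhibitor of the ATP synthase, and 3 fell, Ndufs8 (-0.44), Ndufb5 (-0.43) and Uqcrfs1 (-0.38), with adjusted p = 0.369 with an estimated correlation and the same counts adjusted over the list alone. At least 1 other probe set of each of these 4 genes did not pass. In the TCA cycle list 3 of 14 fell, Pdk1 (-0.75), Dlst (-0.47) and Dlat (-0.41), and 5 adjusted over the list alone (adjusted p = 0.312 with an estimated correlation). In glucose uptake and glycolysis 5 of 17 fell, among them Slc2a1 (-1.96) and Eno3 (-1.60), and Pfkp, a platelet-type phosphofructokinase, rose by 1.53, while adjusted over the list alone 6 fell and 1 rose (adjusted p = 0.159 with an estimated correlation). Another Hk2 probe set gave -4.16 where the main one gave -0.83. In fatty acid oxidation 5 of 17 rose, such as Decr1 (1.27) and Eci1 (0.72), and 2 fell, one of them Echs1 (-1.17), while adjusted over the list alone 7 rose and 2 fell (median 0.01, mean 0.16, adjusted p = 0.0949 with an estimated correlation). Of the proteasome and ubiquitin ligase genes 1 of 25 fell, Psmd1 (-0.52), and 1 adjusted over the list alone (adjusted p = 0.360 with an estimated correlation). Of 12 glucocorticoid responsive genes 3 rose, Pdk4, Cebpd (1.34, other probe sets -0.05 to 3.06) and Txnip (1.14), and adjusted over the list alone 3 rose and 1 fell (adjusted p = 0.338 with an estimated correlation).

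**Figure D5:**
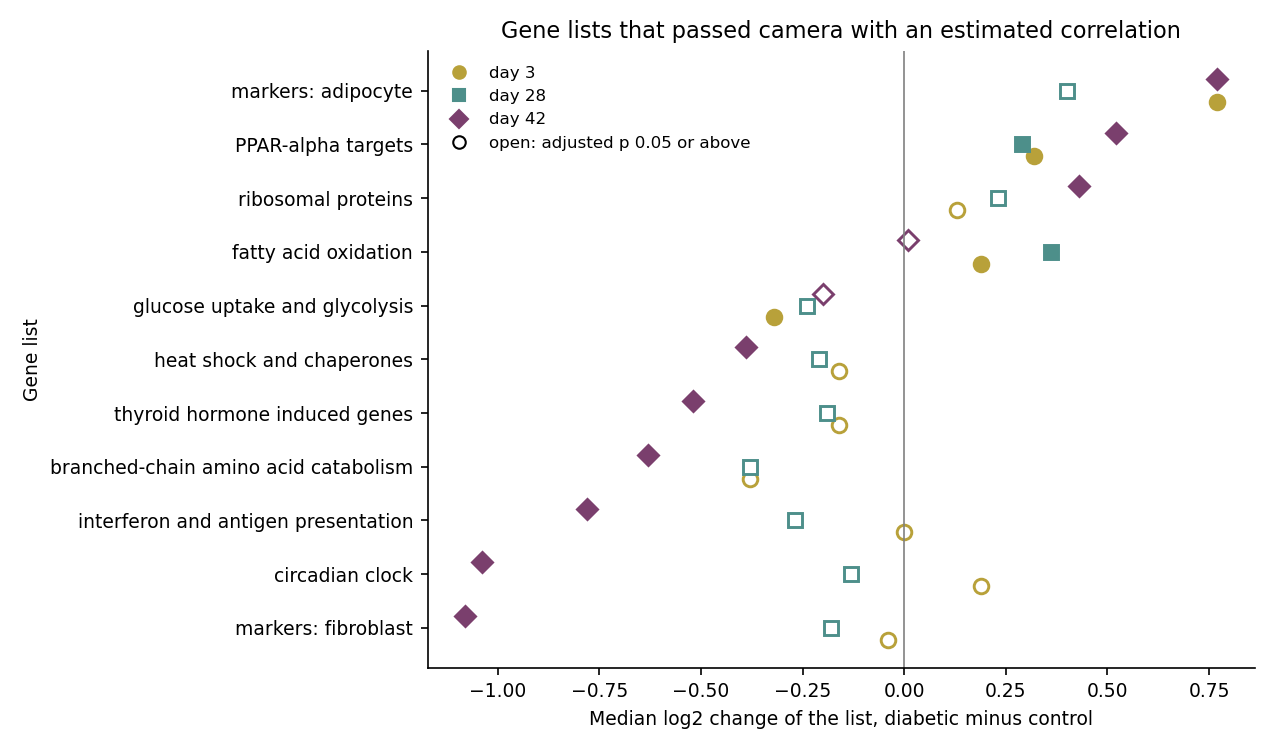
Median log2 change (diabetic minus control) of the members of 11 gene lists at each day, with filled points where the adjusted p was under 0.05 with an estimated correlation and open points where it was not. PPAR-alpha targets had medians of 0.32, 0.29 and 0.52 at days 3, 28 and 42, and fibroblast markers -1.08 at day 42.

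At day 42 limma called 599 probe sets, 304 higher and 295 lower in diabetic ventricles, and 1037 were fully separated (19.8%, where chance gives 2.86%). The count was 561 with fluidics station as a block, which ended the calls of 3 of 63 named genes (Nr4a1, Me1 and Cidea), 402 within station 1 and 61 within station 2, where 599 and 598 of the 599 kept their sign, and single arrays left out gave 477 to 573. The 599 were picked in these same arrays, so signs kept within a station are no independent check. All arrays of day 42 shared 1 scan day and 1 chip lot. Auh, Cfd, Cidea, Ddc, Dlat, Fabp4, Me1, Ndufb5, Ndufs8, Nr4a1 and Uqcrfs1 were no longer past the threshold without one or other array, and the other 52 of the 63 stayed past it. For Cfd the array was control replicate 4 (1.43), for Auh control replicate 1 (-0.46) or diabetic replicate 3 (-0.36), and for Uqcrfs1 control replicate 2 (-0.33), diabetic replicate 2 (-0.36) or diabetic replicate 3 (-0.35), while the others were lost without at least 4 of the 8 arrays.

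More probe sets recurred between days than independent calls would give. Both day 3 and day 28 had 21 higher (0.43 expected if the calls were independent) and 8 lower (0.13 expected), and days 28 and 42 shared 59 higher (3.9 expected) and 37 lower (2.4 expected), with 2 in opposite directions. Days 3 and 42 shared 27 higher (1.9 expected) and 12 lower (0.9 expected), with 2 in opposite directions. At all 3 days 20 were higher and 8 lower. Acot1, Penk, Pik3c2g, Pdk4, Acot2, Decr1 and Cpt1a rose and Slc2a4 and Pcca fell at each day. The days have separate controls, but the fit shares 1 variance estimate per probe set over all days. A probe set with a small variance is called more easily at each day, so the calls are not independent.

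Tested directly, the diabetic effect differed between day 42 and the earlier days mainly where genes were lower in diabetic than control ventricles at day 42. Such a difference can arise from a change in the controls, in the diabetic animals or in both. From day 3 to day 42 Hspa1a rose by 4.1 and Pdk4 fell by 2.69 in controls, while RT1-Da fell by 3.11 in diabetic animals. Against day 28 the largest differences were in LOC102553868 (-4.05 ± 0.74, SE, adjusted p = 0.0038, limma; -4.06 to -2.88 with other floors), Kcnd3 (-3.76 ± 0.60, -3.75 to -2.50 with other floors), Hspa1a (-3.74 ± 0.80, adjusted p = 0.016), Dbp (-3.24 ± 0.43) and RT1-Da (-2.68 ± 0.32). With those floors Hspa1a ran only from -3.74 to -3.66, so the rank of the first 2 depends on the floor. Hspa1a did not pass without control replicate 1 of day 28 (-3.51). Differences in the other direction were Ucp3 (1.48), the transporter gene Slc41a3 (1.4), Anxa5 (0.90) and the lysosomal protease gene Ctsl (0.89). Against day 3 the largest were LOC102553868 (-4.28, -4.28 to -3.29 with other floors), Hspa1a (-4.16, adjusted p = 0.0059), Dbp (-3.80, adjusted p = 5.9e-06), RT1-Da (-3.05) and the clock repressor Nr1d2 (-2.51), and upward Igfbp3 (1.92), Pdk4 (1.90, adjusted p = 0.026), the imprinted RNA H19 (1.65), Cyp2e1 (1.62) and Pfkp (1.49). Of the 16 fits that left out an array of the days compared, 11 ended the call of Ucp3 and 10 that of Slc41a3 against day 28, and 13 ended that of Nr1d2, 10 that of Pdk4 and 9 that of Cyp2e1 against day 3. By list, a test chosen after the data were seen, clock genes differed between day 42 and day 28 by a median of -0.96 (camera adjusted p = 4.1e-05, adjusted p = 0.035 with an estimated correlation) and fibroblast markers by -1.01 (camera adjusted p = 1.2e-07, adjusted p = 0.035 with an estimated correlation). Against day 3 the medians were -1.63 and -1.15 (adjusted p = 0.0042 and adjusted p = 0.034 with an estimated correlation). Between day 42 and day 28 the camera calls of heat shock, antigen presentation, extracellular matrix and fatty acid oxidation genes were lost with an estimated correlation (adjusted p = 0.065 for each). So were those of the thyroid hormone induced, ribosomal, branched-chain catabolism, sarcomere, red cell, glucocorticoid responsive and oxidative phosphorylation lists (adjusted p = 0.089 to 0.54). Against day 3 the lost camera calls were antigen presentation, PPAR-alpha targets, ribosomal proteins, heat shock, extracellular matrix, branched-chain catabolism and red cell markers (adjusted p = 0.056 to 0.34).

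The effect differed in 51 probe sets between days 42 and 28 (9 upward, 42 downward) and in 98 between days 42 and 3 (30 upward, 68 downward). The second count was 64 without control replicate 1 of day 3, 62 without diabetic replicate 4 of day 3, 63 without control replicate 4 of day 42 and 65 without diabetic replicate 2 of day 42. Between days 28 and 3 limma called 0 probe sets, with 243 at an unadjusted p under 0.05 where 262 would be expected by chance. That count was 1 without diabetic replicate 3 of day 3 or control replicate 4 of day 28, and 1 with scan day as a block.

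The change of control animals from day 3 to day 42 served as a background. It mixes growth with scan day, chip lot and operator, which also differed between these days. In controls from day 3 to day 42, Hspa1a rose by 4.10 ± 0.56 (SE, 17.2-fold, adjusted p = 4.0e-05, limma), from 1240 ± 609 to 20100 ± 3960 intensity units (SD, n = 4), and Dbp rose by 2.75 ± 0.31 (adjusted p = 2.4e-06). The acetylcholine receptor gene Chrna1 (1.95), LOC102553868 (1.91) and the collagen hydroxylase gene P4ha1 (1.88) followed. Gpam, which starts triglyceride synthesis, fell by 2.85 ± 0.42 (adjusted p = 4.3e-05), Pdk4 fell by 2.69 ± 0.32, Gja1, the gap junction protein connexin 43, fell by 2.63 ± 0.29, and Rps24 (-2.57) and the bicarbonate transporter gene Slc4a4 (-2.30, -2.30 to -1.53 with other floors) fell as well. In diabetic animals over the same span Acot1 (2.63 ± 0.58, adjusted p = 0.0029), Cyp2e1 (2.58), C2cd4b (2.38), Serpina3n (1.86) and Cdo1 (1.79) rose. Col3a1 fell by 3.45 ± 0.27 (10.9-fold lower, adjusted p = 3.3e-09), and RT1-Da (-3.11), the potassium channel gene Kcnq1 (-2.99), the chemokine gene Ccl5 (-2.95) and Acadsb (-2.64) fell too. With other floors these 3 ran from -2.99 to -2.05, -2.95 to -2.25 and -2.64 to -2.01, so their ranks depend on the floor.

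With age 940 probe sets passed in controls (367 higher, 573 lower at day 42) and 1026 in diabetic animals (443 higher, 583 lower). With median centring the diabetic split was 668 higher and 468 lower, so the balance of rises and falls depends on the scaling. Without diabetic replicate 4 of day 3 the diabetic count was 676. With chip lot as a random block the counts were 351 and 340. Operator 1 ran all arrays of day 42 and operator 2 those of days 3 and 28. No scan day held arrays of more than 1 harvest day, so harvest day, scan day and operator cannot be told apart in these comparisons.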

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

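Tests of the heat shock, clock and collagen patterns were chosen only after the result was seen, except the test of acute handling, whose prediction was fixed beforehand.

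Heat shock genes were lower in diabetic than control ventricles at day 42, with a median of -1.30 over the 7 members past the threshold. The fluidics station is argued against, since the median was -1.14 in the station with the smaller change and -1.46 in the other. These 7 genes lay -0.13 (median, quartile range 0.64) from the controls of days 3 and 28 in the diabetic ventricles of day 42 and 1.35 above them in the controls of day 42, so a fall in diabetic hearts and a rise in the day 42 controls cannot be told apart, because each harvest day was scanned apart. Acute handling of the day 42 controls may contribute: 13 immediate early genes lay a median of 0.52 above the earlier controls, just past the bound of 0.5, though their quartile range was 0.77 and 3 lay below. An effect of diabetes on the chaperone response stays open and was not tested.

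Clock output genes Dbp, Bhlhe41 and Bhlhe40 were lower in diabetic ventricles at day 42, with a median of -1.83. Against the controls of days 3 and 28 their median was -1.30 in diabetic ventricles of day 42 and 0.53 in controls of day 42. For Dbp the values were -1.36 and 1.58. From day 3 to day 42 in controls, 5 of 8 clock genes rose (median 1.05, camera adjusted p = 0.00029, adjusted p = 0.074 with an estimated correlation). The fluidics station is argued against, with -1.74 in the station with the smaller change. A different clock phase at harvest is a candidate explanation, since both probe sets of Bmal1, which peaks opposite to Dbp, were higher in diabetic ventricles (median 1.82, adjusted p = 0.048 and adjusted p = 0.0039, limma). The size rests on the floor, at which all 4 day 42 controls lay for one probe set: with other floors the median ran from 0.84 to 2.10, and with the highest floor neither probe set passed (adjusted p = 0.21 and adjusted p = 0.068). Whether the phase differed because groups were collected at different times of day cannot be told apart from an effect of diabetes, since 0 collection hours were used here. Bmal1 was also lower in controls at day 42 than at day 3, by -4.52 in the probe set with 0 of these control arrays at the floor (-4.52 to -3.08 with other floors).

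Collagen genes were lower in diabetic ventricles at day 42, with a median of -1.92 over 6 genes. The fluidics station is argued against, with -1.71 in the station with the smaller change. Whether fewer fibroblasts account for part of it is undecided: 5 fibroblast markers that are not collagens had a median of -0.47 with a quartile range of 0.52. Of these, Lum (-1.67) and Dcn (-0.49) are matrix genes themselves, so they cannot separate fewer cells from lower matrix expression. The cell markers Thy1 (-0.47), Pdgfra (0.03) and Tcf21 (0.47) went both ways and did not pass. Lower collagen transcription in diabetic hearts stays open and was not tested.

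Single animals lay far from the other 3 of their group in 24 of 446 groups tested, by the gap to the nearest neighbour over the range of the group (Dixon's test at the 95% level), and chance gives about 1 in 20 groups. Among animal and array measures the ratio was 0.831 for the highest body weight in controls at day 42, 1.00 for the highest ventricle weight in controls at day 3, 0.924 for the lowest ventricle to body weight ratio in controls at day 28, and 0.844 for the highest actin 3' to 5' ratio in diabetic arrays at day 28. Among named genes in diabetic ventricles at day 3 it was 0.855 for the highest Pfkfb2, 0.865 for the highest Hspd1, 0.918 for the highest Pex11a and 0.848 for the lowest Rpl21. In controls at day 3 it was 0.912 for the lowest Ccng1, 0.832 for the lowest Rps16, 0.894 for the lowest Decr1, 0.867 for the highest Hadhb, 0.963 for the highest Cd36 and 0.870 for the highest Alox15. In diabetic ventricles at day 28 it was 0.873 for the highest Nppb and 0.899 for the highest G0s2. In diabetic ventricles at day 42 it was 0.917 for the highest Hsph1, 0.859 for the highest RT1-Bb, 0.873 for the highest Ndufs8, 0.927 for the lowest Auh and 0.830 for the lowest Cpt1b. In controls at day 42 it was 0.840 for the lowest Slc2a1, 0.881 for the lowest Bhlhe41 and 0.952 for the highest C2cd4b.

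Differences of the diabetic effect between day 42 and day 28, tested as an interaction in limma, passed in these named genes. Heat shock genes differed by -3.74 (Hspa1a), -2.37 (Dnajb1), -1.82 (Hsph1) and -1.55 (Dnaja1), and clock genes by -3.24 (Dbp) and -1.70 (Bhlhe41). Matrix genes differed by -2.44 (Col3a1), -1.88 (Col1a2), -1.81 (Col1a1), -1.51 (Lum) and -1.48 (Col15a1), and class II genes by -2.68 (RT1-Da), -1.91 (Cd74) and -1.50 (RT1-Db1). LOC102553868 (-4.05), Kcnd3 (-3.76), Ucp3 (1.48), Slc41a3 (1.4), Anxa5 (0.90) and Ctsl (0.89) passed as well. The clock list differed by a median of -0.96 and the fibroblast markers by -1.01.

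Between day 42 and day 3 the same test passed for heat shock genes Hspa1a (-4.16), Dnajb1 (-1.85), Hsph1 (-1.81) and Dnaja1 (-1.39), and for clock genes Dbp (-3.80), Nr1d2 (-2.51), Bhlhe41 (-2.13) and Per2 (-2.04). It passed for matrix genes Col3a1 (-2.38), Col15a1 (-2.04), Col1a1 (-1.60), Col1a2 (-1.59) and Lum (-1.56), and for class II genes RT1-Da (-3.05), Cd74 (-1.88), RT1-Db1 (-1.81) and RT1-Bb (-1.35). Other downward differences were LOC102553868 (-4.28), Acsl6 (-2.0) and Pxmp2 (-0.85). Upward differences were Igfbp3 (1.92), Pdk4 (1.90), H19 (1.65), Cyp2e1 (1.62), Pfkp (1.49), Slc41a3 (1.39) and Rpl19 (0.55). The clock list differed by a median of -1.63 and the fibroblast markers by -1.15. The effect on the ventricle to body weight ratio differed by 1.08 mg/g, past the threshold in the permutation within days, which does not test for equal effects.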

How the results depend on the processing

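Chip lot blocks, fits within single batches, batch fits of gene lists, random blocks for the comparisons with age and the fit without the 2 arrays that deviate most were chosen only after the data were seen. In the totals that follow, the random blocks for replicate and scan day are counted with the settings fixed beforehand. Over the settings fixed beforehand, 4898 of 5375 values of named genes kept their side of the threshold, and their direction where past it, 443 fell short of it, 34 newly passed and 0 reversed. For added ones the numbers were 791, 240, 7 and 0 of 1038. Of 1443 such list values 1358 kept both, 53 fell short and 32 newly passed, and of 555 added ones 493 kept both and 2 reversed by the direction camera gives: oxidative phosphorylation at day 3 within station 2 (median -0.04, the sign of the full fit) and ribosomal proteins at day 3 within chip lot 4 (-0.06). Medians also turned, without a reversed direction, for the clock (-0.12, station 2) and complement (-0.03 with a station block, -0.05 in station 2) at day 3 and for fatty acid oxidation at day 42 (-0.03 without diabetic replicate 4, -0.01 with a station block). For the animal measures, 0 of the 108 alternatives counted as moved. Leaving out 1 of 4 animals cannot shift a mean beyond the pooled SD, which was the bound, so those fits were no check. With 3 against 4 animals the exact p cannot fall below 0.05 either. The fits on log2 values were judged by their p-value instead. The ventricle to body weight ratio at day 28 (-0.0133, not past the threshold) turned sign without control replicates 1, 2 or 4 (0.00783, 0.00683 and 0.0142). Low signals limit Acot1, LOC102553868, Acsl6, C2cd4b, Kcnd3, Kcnq1, Slc4a4, Ccl5, Acadsb and Bmal1, whose size depends on the floor; other floors for Bmal1 were tried after the data were seen.

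Counts moved over 1.5 times as follows. With 1 probe set per gene, where fewer were tested, they were 58 at day 28, 346 at day 42, 1, 29 and 56 for the differences 28 against 3, 42 against 28 and 42 against 3, and 500 and 614 for age in controls and diabetic animals. At an adjusted p under 0.01, by construction, they were 20, 60 and 375 at days 3, 28 and 42, and the overlaps were 12 (days 3 and 28), 57 (28 and 42) and 15 (3 and 42). For the rest the cause was not tested. A fluidics station block gave 23 at day 3 and 49 at day 28. A scan day block gave 20 at day 3 and 1 for 28 against 3. Plain eBayes gave 32 and the fit without the most deviating arrays 75 at day 3. A fit of only the groups compared gave 49 at day 28 and 1432 for age in controls. A random chip lot block gave 351 and 340 for age in controls and diabetic animals. Fits within batches, with fewer arrays, gave 3 (scan day 4), 5 (station 2), 31 (lot 4) and 2 (lot 5) at day 3, 16 (station 2) and 51 (lot 2) at day 28, and 61 (station 2) at day 42; a lone array of a group is assumed to vary like the others.

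The number of lists past the threshold was 4, 2 and 9 at days 3, 28 and 42 with an estimated correlation, against 13, 5 and 16. It was 8 within station 2 and 7 within lot 4 at day 3, and 8 within station 2 at day 28. Replicate numbers did not pair the arrays (correlations of same-number arrays -0.189 to 0.397). With replicate as a block the counts were 43, 109 and 624 at days 3, 28 and 42, 0, 47 and 103 for the differences, and 8 lists at day 28; as a random block they were 944 and 1019 with age.

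Leaving out each array in turn gave 17 to 62 at day 3, 79 to 116 at day 28 and 477 to 573 at day 42. It gave 0 to 1 for 28 against 3, 41 to 65 for 42 against 28, 62 to 104 for 42 against 3, 629 to 822 with age in controls and 676 to 1396 in diabetic animals. Lists past the threshold ran from 11 to 17, 4 to 7 and 12 to 18, and no list that held with an estimated correlation lost its camera call in these fits.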

Other observations

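Tests of fewer macrophages and of recurring calls and the genes named in the next paragraph were chosen only after the result was seen, and the splits of the arrays and the test of a younger profile were fixed beforehand.

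In the antioxidant and detoxification list 4 of 27 genes rose at day 42, all glutathione S-transferases, which conjugate glutathione to reactive compounds, with Gstt2 at 1.34, Gstm1 at 1.03, Gsta4 at 0.99 and Gstp1 at 0.85, while the mitochondrial Txnrd2 (-0.56) and Prdx3 (-0.44) fell. Adjusted over the list alone 5 rose and 2 fell, and the list as a whole did not pass (camera adjusted p = 0.154). Of 14 genes of potassium channels and conduction 2 fell at day 42, Kcnd3 (-2.40) and Kcnq1 (-2.08), subunits of channels that repolarise the heart, and 2 adjusted over the list alone (camera adjusted p = 0.686). Fetal and hypertrophic genes went both ways at day 42, with Nppa (2.30), Myc (1.06) and the slow skeletal troponin gene Tnni1 (0.98) higher and Slc2a1 (-1.96) and the skeletal actin gene Acta1 (-1.34) lower (3 and 2 of 14, the same counts adjusted over the list alone, camera adjusted p = 0.599). Of 9 lipogenesis genes 4 fell, Scd2 (-1.79), Elovl5 (-0.63), Dgat1 (-0.60) and Me1, and Acacb rose (0.71), while adjusted over the list alone 4 fell and 2 rose (camera adjusted p = 0.392).

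Markers of most other cell types did not pass at day 42. Macrophage markers had a median of 0.26 over 6 genes (camera adjusted p = 0.163), lymphocyte markers -0.14 over 5 (0.809), endothelial markers 0.07 over 7 (0.305) and smooth muscle markers 0.12 over 4 (0.530). Kdr, the VEGF receptor of endothelial cells, rose by 1.83 alone among the endothelial markers. With age, by a list test chosen after the data were seen, matrix genes were lower at day 42 than at day 3 in both groups: 9 of 26 fell in controls (median -0.42, camera adjusted p = 0.00029, adjusted p = 0.45 with an estimated correlation), and 13 fell and 2 rose in diabetic animals (median -0.57, camera adjusted p = 9.8e-09, adjusted p = 0.078 with an estimated correlation). Fibroblast markers were lower in diabetic animals (median -1.34, camera adjusted p = 1.6e-06, adjusted p = 0.078 with an estimated correlation) and endothelial markers in controls (median -0.90, camera adjusted p = 0.038, adjusted p = 0.63 with an estimated correlation). The hexokinase 3' to 5' ratio was higher at day 42 too, so age, scan day and RNA quality cannot be told apart here.

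A loss of macrophages, cells that carry much MHC class II, was tested as a cause of the lower class II genes at day 42. The 7 class II genes, Cd74 included, had a median of -1.35, while 6 macrophage markers had a median of 0.26 (quartile range 0.15) and 0 of them lay below 0, which argues against it. Fewer class II transcripts per cell, or the loss of another cell type, stay open and were not tested.

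A younger profile in the smaller diabetic hearts was tested by correlating, across 3140 genes, the diabetic change with the change of controls with age, using different days for each. Genes are not independent replicates, so the arrays were regrouped. For the diabetic change at day 42 Pearson's r was -0.12 (Spearman's rho -0.11), and 4 of 70 arrangements were as low (exact one-sided p = 0.057). For the diabetic change at day 28 r was -0.18 (rho -0.18), and 9 of 70 were as low (exact one-sided p = 0.13). The hypothesis was not borne out.

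Other splits of the same arrays showed where chance can be excluded as the source of a count. At day 42, 1 of 35 splits gave as many calls (599, highest other 2), so chance can be excluded, as for age in controls (1 of 35, 940, highest other 3) and in diabetic animals (1 of 35, 1026, highest other 298). At day 3 chance cannot be excluded for the count alone: 2 of 35 splits gave as many as 49, and the highest other gave 149, with control replicates 1, 2 and 3 and diabetic replicate 1 against the rest. That split follows chip lots 4 and 5 and points to a structure of the samples, and the count was 40 with chip lot as a block, 31 within lot 4 and 2 within lot 5. At day 28 chance cannot be excluded for the count alone either: 2 of 35 splits gave as many as 110, with 115 as the highest other. No recorded batch divided the arrays of day 28 into 4 and 4, so no split could follow one exactly. The highest split set apart control replicates 1 and 3 and diabetic replicates 2 and 3. These were the 4 arrays of that day with the highest mean signal (2388 to 2655 against 2254 to 2339). Chance can be excluded for the calls that recurred in the same direction in other animals: 29 of day 3 recurred at day 28 (1 of 35 splits, highest other 2) and 96 of day 28 at day 42 (1 of 35 splits, highest other 8). For the differences between days, 3 of 100 splits reached 51 for day 42 against day 28 (highest other 185). For day 42 against day 3, 3 of 100 reached 98 (highest other 402). These splits regrouped the arrays of both days, so they test for no diabetic effect at either day. They cannot decide whether the effect differed between days. Both highest splits kept the true groups at day 42 and mixed those of the other day (2 of 4 controls on each side at day 28, 3 and 1 at day 3). A day 42 effect set against mixed groups thus gave larger counts than the real groups. The make-up of the other splits that reached the real counts was not examined. For day 28 against day 3, all 100 splits gave at least 0 (highest other 65). By lists past the threshold, no other split of day 3 gave as many as the real groups (13 lists, highest other 11). That share, 1 of 35, is the smallest these splits can give. Leaving out single arrays gave 11 to 17 lists, which reaches the highest other split, and 9 of the 13 were lost with an estimated correlation. Chance is thus not firmly excluded for this count. Nor can it be excluded at day 28 (11 of 35, 5 lists, highest other 7) or day 42 (3 of 35, 16 lists, highest other 16).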
